A study of Homo sapiens with 10 samples.

How the data were processed

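CD3+CD4+CD8- T cells from the blood of 5 healthy donors were sorted by CD57 and PD-1, and RNA of the CD57pos (CD57+PD1-) and CD57neg (CD57-PD1-) cells of each donor was hybridised to 1 Affymetrix U133 Plus 2.0 array each, 10 arrays in all. Per the labels' protocols, total RNA was purified with RNeasy Micro columns and DNase, and amplified and labelled with the NuGEN Ovation Pico system. The deposited values are log2 expression after normalization across the samples by the robust multichip average (RMA), per the series' design text and the submitters' processing notes, which also name Partek 6.5. The background and summary options of RMA are not given in the sources used here. All 10 columns were on the same scale, with medians between 5.89 and 5.99 and values from 1.04 to 14.02.

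The table held 54675 probe sets, of which 62 controls were left out. The annotation table gave 1 gene symbol to 41091 probe sets, several to 1801 and none to 11721; genes were named from probe sets with 1 symbol alone. Genes of the Y chromosome, XIST and TSIX were left out, which left 41018 probe sets of 19732 genes. Each gene was given the values of its probe set with the highest mean over the 10 arrays. Genes were tested where that mean was at or above 5.93, the median of all probe sets' means, which kept 11176 genes. Among the named genes, 60 of 71 other probe sets above the filter had the direction of the reported one and 11 the opposite, in ATP5F1A, CD28, FOXP3, ITGA4, MCM4, NDUFA6, SKIL and TERF2. PDCD1, the gene of PD-1, and several members of the lists were not analysed here.

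Genes were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the deposited log2 values, with the donor as a fixed block and Benjamini-Hochberg adjustment at 0.05. The donor pairs the samples because the blood of each donor was sorted into both populations. The deviations of the 2 arrays of a donor from their group means correlated across genes at 0.206, 0.214, 0.0822, 0.0457 and 0.255, and each CD57pos array correlated best with the CD57neg array of its own donor. With 5 donors an exact two-sided sign-flip test of 1 value could not give a p under 0.0625, so single values are given with limma's adjusted p. Errors given with differences are limma's standard errors (SE); a difference is CD57pos minus CD57neg on the log2 scale, and a fold is 2 to the power of its size, given only where the means of both groups lay at or above the filter.

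Fixed gene lists, 35 in number, were tested with limma's camera with a preset correlation of 0.01, adjusted over the 33 lists with at least 3 measured members. Adjusted values of a list's members were also computed over the list alone. The lists were genes of the sort gate; cytotoxic effector genes; NK-type receptors and adaptors; costimulatory receptors and ligands; coinhibitory receptors; naive and central memory genes; effector and terminal differentiation transcription factors. They also held integrins and adhesion molecules, chemokine and sphingosine phosphate receptors, genes of Th1, Th2, Th17, regulatory and follicular helper T cells, proliferation genes, cell cycle inhibitors and senescence genes, T cell receptor signalling components, and common gamma chain cytokine receptors and mediators. Further lists were apoptosis regulators, TGF-beta signalling genes, class II MHC and activation genes, type I interferon response genes, ribosomal protein genes, oxidative phosphorylation genes, glycolysis genes, and immediate early and handling stress genes. Markers of NK cells, CD8 T cells, gamma delta and invariant T cells, B cells, monocytes and myeloid cells, neutrophils, platelets, red blood cells and plasma cells stood for other cell types. Some genes stand on several lists: SLAMF7, CD58 and CD226 count under each of theirs.

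The text names up to 14 genes per direction that pass limma's test (there were 0), the genes of the sort gate, and CD28, CD2, CD58, CD27, ITGAL, ITGB2, ITGA4, GZMB, PRF1, TBX21, EOMES, CCR7 and KLRG1 whatever their values. Of each list it names up to 4 members with the smallest adjusted p. Variable segments of immunoglobulin and T cell receptor genes, HLA-DR B and HLA-DQ genes and provisional symbols are never named. Lists, filter, tests, the rule for named genes and most alternatives were fixed before the data were examined.

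Alternatives were no filter on dim probe sets, a stricter filter at a mean of 7.07, the mean of all probe sets of a gene, each probe set on its own, median centring, quantile normalization, no donor block, the donor as a random block (duplicateCorrelation with statmod 1.5.0), an intensity trend or robust estimation in the prior, a plain paired test per gene, each range of array facility numbers alone, and each donor left out. For the lists, camera with an estimated correlation and fry were run as well. Array quality weights, donors 1, 2 and 5 only, and donors 2 and 5 only were added after the data were seen. The tests were also run on simulated data with the measured spread of 11176 genes, for CD57pos against CD57neg. There limma called 57% of 100 genes changed by a log2 difference of 1 and 90% of 100 changed by 2. It made 5 wrong calls and 0 of wrong sign, and camera called 2 of 2 shifted lists and 0 of the unshifted ones. The simulated genes were independent, with normal errors of the same SD in both groups. On the real arrays 76.3% of genes had the larger SD in CD57pos cells, and members of a list can vary together. The simulated rates therefore need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.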

Results

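Gene expression was measured in CD4 T cells sorted from the peripheral blood of 5 healthy donors. The sort used CD57, a carbohydrate epitope found on NK cells and on T cells late in differentiation, and PD-1, an inhibitory receptor of activated T cells. Cells with CD57 and without PD-1 (the CD57pos group) were compared with cells that carried neither (the CD57neg group). Each donor gave 1 Affymetrix U133 Plus 2.0 array of each group, 5 arrays per group and 10 in all. Values are log2 expression, and the median over all probe sets of an array lay between 5.89 and 5.99. The number of arrays limits the precision of every value.

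Transcripts of CD4 and of the CD3 chains, genes of the sort gate, lay at close levels in both groups. CD4, the coreceptor that defines these cells, stood at 10.87 ± 0.07 in CD57pos and 10.86 ± 0.06 in CD57neg cells (SD, n = 5), and CD3E, a chain of the CD3 complex, at 11.12 ± 0.11 and 10.98 ± 0.16. The log2 difference, CD57pos minus CD57neg, was -0.03 ± 0.13 (SE) for CD3D and 0.04 ± 0.17 for CD3G, or -0.13 and -0.12 without replicate 4; that of CD3D was above 0 when each array was centred on its median. CD8A, the coreceptor of cytotoxic T cells that the sort excluded, lay at 7.15 ± 0.81 and 7.14 ± 1.03 (SD, n = 5), with differences between -1.18 and 2.75 over the donors, and CD8B at 6.19 ± 0.74 and 6.54 ± 0.62, with a log2 difference of -0.35, or 0.10 without replicate 3. Without replicate 4 the differences of CD8A and CD8B were -0.68 and -0.70. B3GAT1, the glucuronyltransferase that builds the CD57 epitope, lay at 5.85 ± 0.65 and 4.58 ± 0.23, higher in 5 of 5 donors with a log2 difference of 1.26 ± 0.27 (SE). It was dimmer than the filter allowed and had limma's adjusted p = 0.17 without the filter. Of the 6 gate genes measured above the filter, 0 passed limma's test adjusted over the list alone. Their median difference was 0.01, or -0.12 without replicate 4, their mean -0.03 and camera's direction up, with adjusted p = 0.812.

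In all 5 donors, CD57pos cells had higher GZMB, PRF1, SLAMF7, EOMES and TBX21, genes of killing and of effector differentiation, and lower CCR7, NOG and MYC, genes of less differentiated T cells. No single gene passed the test over all genes. With limma and the donor as a block, 0 of 11176 genes were higher and 0 lower after adjustment, and the smallest adjusted p was 0.112. At an unadjusted p under 0.05, 650 genes were higher and 966 lower. That split was 784 higher and 771 lower when each array was centred on its median, and 865 and 803 after quantile normalization. Without the filter on dim probe sets it was 1764 higher and 1352 lower of 19732 genes, with 0 past adjustment. The same direction in all 5 donors was seen for 868 genes that were higher and 1020 that were lower, 16.9% of those tested, where chance gives 6.25%. Of these, 97 were higher and 83 lower by a log2 difference of 1 or more.

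Fits of other kinds called some genes. EOMES, the adhesion receptor ADGRG1 and the receptor SLAMF7 passed without the donor block, with the donor as a random block, and with array quality weights, a fit added after the data were seen. Their adjusted p with the random block was 0.0139, 0.0273 and 0.0309. limma called 6 genes higher and 2 lower without the block, 38 and 23 with the random block, and 29 and 14 with the weights. Both the random block and the weights called 24 genes. The weights were 0.889, 2.16, 0.537, 0.444 and 2.18 for the CD57pos arrays of replicates 1 to 5, so that fit leaned most on replicates 2 and 5. With 2 arrays per donor and the donor as a block, such weights grade donors rather than single arrays. All other fits called 0 genes. Values varied more among the CD57pos arrays: the median SD over genes was 0.347 there and 0.204 in CD57neg cells. For 76.3% of genes the SD was larger in CD57pos cells. With 1 array per donor and group, variation between donors cannot be told apart from variation between arrays. On the CD57pos arrays of replicates 1, 3 and 4, 73, 163 and 105 genes lay more than 2 log2 below the gene's median over the 10 arrays, against 4 and 4 on the other CD57pos arrays. With donors 2 and 5 only, a choice made after the data were seen, 463 genes were higher and 754 lower at an unadjusted p under 0.05 and 0 passed adjustment.

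Most of the measured cytotoxic genes, 17 of 23, were higher in CD57pos cells by the test over the list alone. GZMH, a granzyme, lay at 11.17 ± 1.41 against 7.63 ± 0.96 (SD, n = 5), an 11.6-fold difference with log2 3.54 ± 0.49 (SE). GZMB, the granzyme that starts apoptosis in target cells, was 5.59-fold higher (log2 2.48 ± 0.54, or 1.81 without replicate 4). PRF1, the pore-forming perforin, was 2.66-fold higher (1.41 ± 0.24). GZMA was 3.61-fold higher (1.85 ± 0.30), and GZMK, a granzyme more usual in less differentiated memory cells, 2.43-fold (1.28 ± 0.17). ADGRG1, an adhesion G protein-coupled receptor carried by cytotoxic lymphocytes, was 7.06-fold higher (2.82 ± 0.36). All 6 were higher in 5 of 5 donors, with limma's adjusted p = 0.154 for GZMB and 0.112 for the other 5. Of the 23 measured cytotoxic effector genes, 17 were higher and 0 lower adjusted over the list alone, against 0 over all genes tested. Their median log2 difference was 1.28, between 1.14 and 1.39 when 1 donor at a time was left out. The list passed camera with the preset correlation of 0.01 (adjusted p = 2.19e-17), and it did not pass at adjusted p = 0.322 with an estimated correlation, nor by fry, the rotation test of a list alone (adjusted p = 0.0723).

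**Figure D1:**
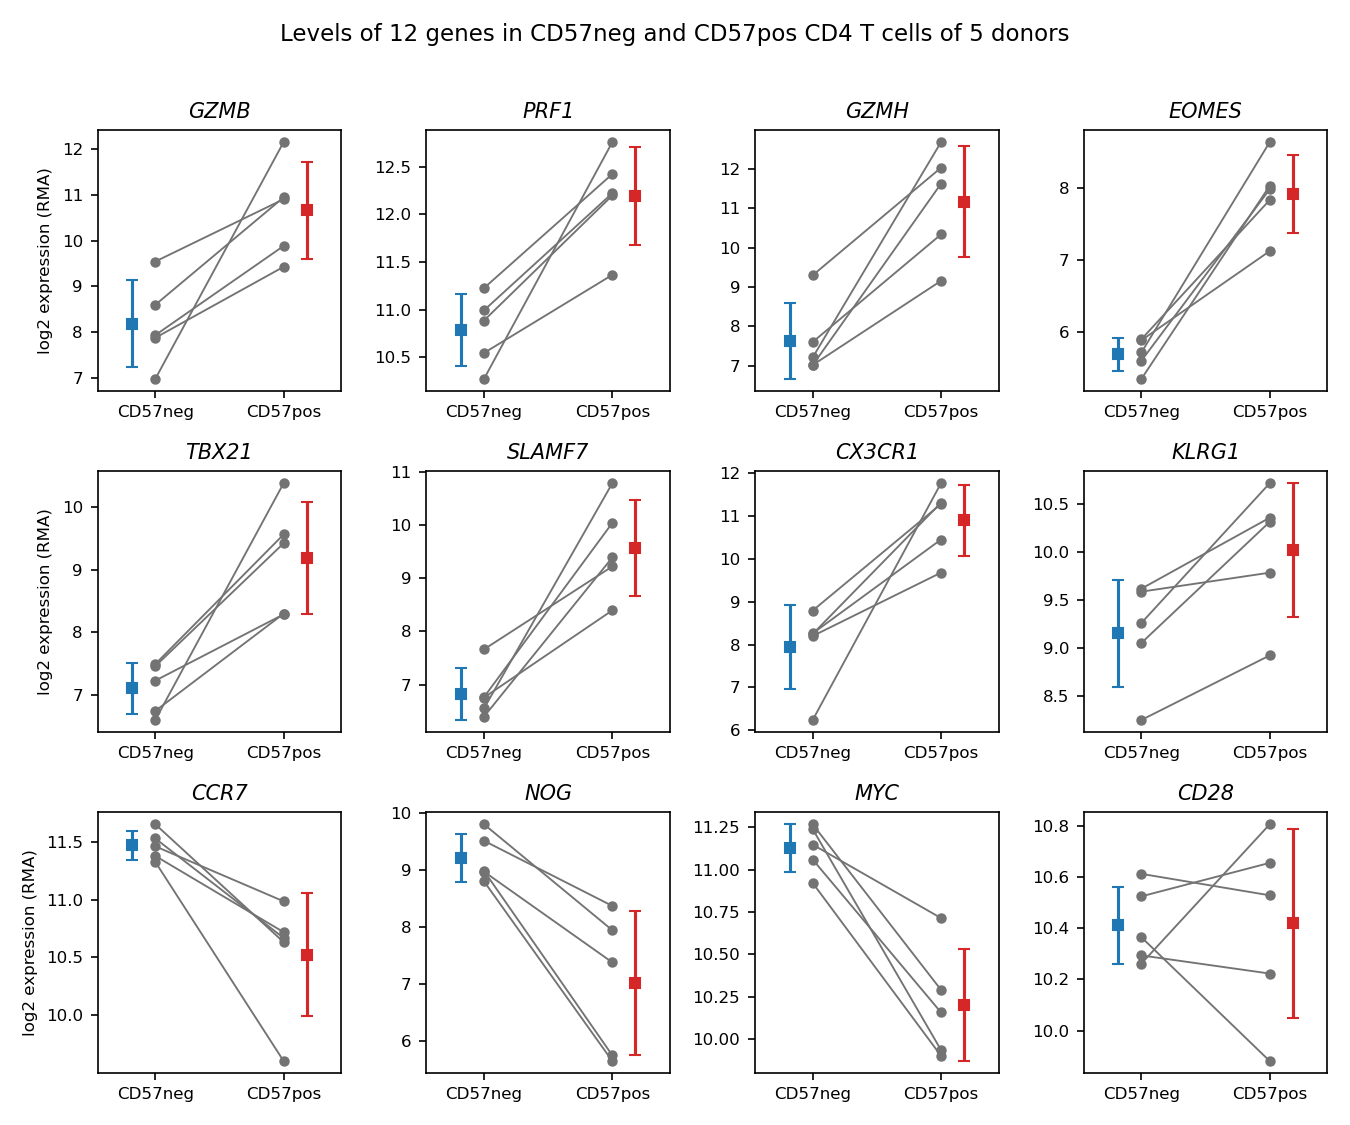
Log2 expression (vertical axes, each with its own range) of 12 genes in CD57neg and CD57pos CD4 T cells. Each grey line joins both arrays of 1 donor, squares with bars are means ± SD of 5 donors, and lines slope one way in all 5 donors for every gene shown except CD28, whose mean log2 difference was 0.01.

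Several markers of NK cells, 6 of 10, were higher too by the test over the list alone. IL18RAP, a chain of the interleukin-18 receptor, was 3.36-fold higher in CD57pos cells (log2 1.75 ± 0.28, SE). PRSS23, a secreted serine protease, differed by 2.87 ± 0.37; its level in CD57neg cells, 5.20, lay below the filter and close to background, so no fold is given. KLRF1, the activating receptor NKp80, was 3.64-fold higher (1.86 ± 0.39), and XCL1, the chemokine lymphotactin, 2.92-fold (1.55 ± 0.35). Of 10 measured NK cell markers, 6 were higher and 0 lower adjusted over the list alone, and 0 over all genes. Their median difference was 1.16, or 0.76 without replicate 4, 0.67 with array quality weights, 0.66 with donors 1, 2 and 5 only and 0.35 with donors 2 and 5 only. camera gave adjusted p = 3.72e-07 and adjusted p = 0.334 with an estimated correlation, and fry adjusted p = 0.106. The sort for CD3 would remove NK cells, but it would also remove monocytes. The monocyte markers LYZ and S100A8 still had medians of 11.2 and 10.8 over the 9 arrays other than the CD57neg array of replicate 4. The gate alone thus does not exclude NK cells.

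Of the receptors and adaptors of the NK type, 12 of 18 were higher in CD57pos cells by the test over the list alone, and 6 did not pass. SLAMF7, a receptor that triggers killing, was 6.67-fold higher (log2 2.74 ± 0.40, SE), KLRG1, an inhibitory lectin-like receptor of late-differentiated T cells, 1.82-fold (0.87 ± 0.20), and CD226, an activating receptor for nectin-family ligands, 1.41-fold (0.49 ± 0.13). Each was higher in 5 of 5 donors (limma's adjusted p = 0.112, 0.169 and 0.191). In this list of NK-type receptors and adaptors 0 members were lower adjusted over the list alone, and 0 passed over all genes. The median difference was 0.77, or 0.44 with donors 2 and 5 only, and camera gave adjusted p = 5.37e-11, adjusted p = 0.322 with an estimated correlation, and fry adjusted p = 0.0974.

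Several transcription factors of effector differentiation followed the same direction. EOMES, which drives cytotoxic programmes in lymphocytes, lay at 7.92 ± 0.54 against 5.69 ± 0.23 (SD, n = 5), a log2 difference of 2.23 ± 0.25 (SE), with no fold given because the level in CD57neg cells was below the filter. TBX21, which encodes the Th1 factor T-bet, was 4.24-fold higher (2.08 ± 0.36), BHLHE40, a repressor needed for cytokine output in effector T cells, 1.87-fold (0.90 ± 0.16), and RUNX3, a factor of cytotoxic lineages, 1.74-fold (0.80 ± 0.16). limma's adjusted p was 0.112 for the first 3 and 0.135 for RUNX3, and each was higher in 5 of 5 donors. Of 17 measured factors of effector and terminal differentiation, 8 were higher and 0 lower adjusted over the list alone, and 0 over all genes. The list's median difference was 0.69, or 0.41 with the mean of all probe sets of a gene, 0.38 with donors 1, 2 and 5 only and 0.34 with donors 2 and 5 only, with camera's adjusted p = 4.43e-08, adjusted p = 0.322 with an estimated correlation, and fry's adjusted p = 0.0957.

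Most genes of naive and central memory T cells, 19 of 25, were lower in CD57pos cells by the test over the list alone, and 6 did not pass. CCR7, the receptor that guides T cells into lymph nodes, lay at 10.52 ± 0.53 against 11.47 ± 0.13 (SD, n = 5), 1.93-fold lower with a log2 difference of -0.95 ± 0.20 (SE). NOG, which encodes the BMP antagonist noggin, was 4.59-fold lower (-2.20 ± 0.34), FHIT, a dinucleotide hydrolase, 2.45-fold (-1.29 ± 0.21), MYC, a driver of growth and proliferation, 1.90-fold (-0.93 ± 0.15), and NELL2, a secreted glycoprotein, 1.88-fold (-0.91 ± 0.15). CD27, a costimulatory receptor that is lost late in differentiation, was 1.55-fold lower (-0.63 ± 0.15). All 6 were lower in 5 of 5 donors, with limma's adjusted p = 0.146 for CCR7, 0.178 for CD27 and 0.112 for the others. In this list 0 measured members were higher adjusted over the list alone, and 0 passed over all genes. The median difference was -0.78, or -0.44 in the lower range of the arrays' facility numbers and -0.51 with donors 1, 2 and 5 only, with camera's adjusted p = 1.62e-12, adjusted p = 0.322 with an estimated correlation, and fry's adjusted p = 0.0723.

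Several Th1 mediators were higher by the test over the list alone, and 6 of 13 did not pass, 4 of the 13 with lower estimates. CCL4 and CCL5, chemokines that attract T cells and monocytes, were 6.49-fold (log2 2.70 ± 0.51, SE) and 2.54-fold (1.35 ± 0.25) higher in CD57pos cells, in 5 of 5 donors (limma's adjusted p = 0.126 and 0.121). Without replicate 4 the log2 difference of CCL4 was 2.07. Of 13 measured genes of Th1 cytokines, chemokines and their receptors, 7 were higher and 0 lower adjusted over the list alone, and 0 over all genes. The median difference was 0.65, or 1.35 with the stricter filter, 0.37 in the lower range of the arrays' facility numbers, 0.43 with array quality weights and 0.41 with donors 1, 2 and 5 only, with camera's adjusted p = 5.39e-05, adjusted p = 0.471 with an estimated correlation, and fry's adjusted p = 0.185.

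Receptors for migration were split. CX3CR1, the fractalkine receptor of cytotoxic lymphocytes in blood, lay at 10.89 ± 0.83 against 7.95 ± 0.98 (SD, n = 5). It was 7.70-fold higher in CD57pos cells (log2 2.95 ± 0.53, SE, or 2.30 without replicate 4). S1PR5, a sphingosine phosphate receptor that keeps effector cells in circulation, was 5.86-fold higher (2.55 ± 0.39). CXCR2, a receptor for interleukin-8, differed by 1.39 ± 0.23 and CCR10, a skin-homing receptor, by 1.17 ± 0.24; both lay below the filter in CD57neg cells (5.87 and 5.86). The adjusted p from limma was 0.119, 0.112, 0.112 and 0.139. Of the 18 measured chemokine and sphingosine phosphate receptors, 7 were higher and 2 lower adjusted over the list alone, and 0 over all genes; CCR7 and GPR15 were those lower. Their median difference was 0.25, or 0.14 without replicate 1, 0.15 without replicate 3, 0.14 in the lower range of the arrays' facility numbers and 0.12 with donors 2 and 5 only, with camera's adjusted p = 0.00861, adjusted p = 0.322 with an estimated correlation, and fry's adjusted p = 0.0429. Without the filter on dim probe sets the median was 0.44 and camera's adjusted p = 0.19, and with the stricter filter or the mean of all probe sets of a gene the list's median was 0.05 (adjusted p = 0.0448 and 0.0257).

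Among costimulatory and adhesion genes, CD58 (LFA-3), the ligand of CD2, was 1.90-fold higher in CD57pos cells, with a log2 difference of 0.93 ± 0.17 (SE) and the same direction in 5 of 5 donors (limma's adjusted p = 0.121). CD28, the main costimulatory receptor of T cells, did not separate the groups: it lay at 10.42 ± 0.37 and 10.41 ± 0.15 (SD, n = 5), with a log2 difference of 0.01 ± 0.17, and its other probe sets above the filter, 2 in number, were lower in CD57pos cells. CD2 differed by 0.30 ± 0.14, ITGAL, the alpha chain of LFA-1, by 0.39 ± 0.12 (5 of 5 donors), its partner ITGB2 by 0.12 ± 0.12 (0.06 without replicate 4), and ITGA4, a chain of VLA-4, by 0.06 ± 0.16 (-0.02 without replicate 4 and 0.19 without replicate 1), with adjusted p from 0.249 to 0.884. ITGAM, the alpha chain of the complement receptor Mac-1, was 3.89-fold higher (1.96 ± 0.40, or 1.52 without replicate 4). Its differences ran from 0.76 to 3.73 over the donors. ITGB1, the beta chain shared by VLA integrins, was 1.35-fold higher (0.43 ± 0.12). CD58 and ITGAM were the 2 of 24 measured adhesion genes that were higher adjusted over the list alone, with 0 lower and 0 over all genes. The adhesion list had a median difference of 0.23 and camera's adjusted p = 0.00129, but adjusted p = 0.322 with an estimated correlation, 0.0957 by fry and 0.125 without the filter. Its median was 0.15 with the mean of all probe sets of a gene, 0.08 with donors 1, 2 and 5 only and 0.08 with donors 2 and 5 only. In the costimulatory list of 22, 3 members (SLAMF7, CD58 and CD226) were higher and 1, CD27, lower adjusted over the list alone, and 0 over all genes. Its median was 0.12, with camera's adjusted p = 0.0214, adjusted p = 0.322 with an estimated correlation, and fry's adjusted p = 0.0429. Leaving out replicate 1, 3 or 5 gave camera's adjusted p = 0.0724, 0.0515 and 0.066 for that list, and no filter on dim probe sets 0.386; with array quality weights its median was 0.07.

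Some of the activation and class II genes were higher in CD57pos cells, and 13 of 21 did not pass over the list alone. LGALS1, the lectin galectin-1 of activated and memory T cells, was 2.38-fold higher in CD57pos cells (log2 1.25 ± 0.27, SE), HLA-DPA1, a class II chain that human T cells express once activated, 1.77-fold (0.82 ± 0.21), ANXA2, a membrane-binding annexin, 1.65-fold (0.72 ± 0.15), and S100A4, a calcium-binding protein of memory cells, 1.49-fold (0.58 ± 0.16). limma's adjusted p was 0.154, 0.185, 0.151 and 0.211, and each was higher in 5 of 5 donors. In this list 8 of 21 measured members were higher and 0 lower adjusted over the list alone, and 0 over all genes. The median difference was 0.48, or 0.26 without replicate 4, 0.24 with array quality weights, 0.30 with donors 1, 2 and 5 only and 0.17 with donors 2 and 5 only, with camera's adjusted p = 6.64e-08, adjusted p = 0.322 with an estimated correlation, and fry's adjusted p = 0.0974. Monocytes carry many of these transcripts. The 16 measured monocyte and myeloid markers had a median difference of 0.41 and camera's adjusted p = 0.0984, and -0.23 without replicate 4.

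Immediate early and handling stress genes went both ways. DUSP2, a phosphatase induced on activation, differed by 1.18 ± 0.25 (SE), FOSB, an AP-1 subunit, by 1.36 ± 0.40, and IER3, an early response gene, by -0.57 ± 0.13, with limma's adjusted p = 0.154, 0.247 and 0.174. Adjusted over the list alone, 1 of 20 measured members (DUSP2) was higher and 1 (IER3) lower, and 0 over all genes. The median was 0.18, with camera's adjusted p = 0.0177, adjusted p = 0.512 with an estimated correlation, and fry's adjusted p = 0.432. Without replicate 1 the median was 0.10 and camera's adjusted p = 0.156, and with donors 2 and 5 only it was -0.04. The call was also lost without the filter on dim probe sets (adjusted p = 0.0995), with array quality weights (median 0.08, adjusted p = 0.221) and with donors 1, 2 and 5 only (adjusted p = 0.125).

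**Figure D2:**
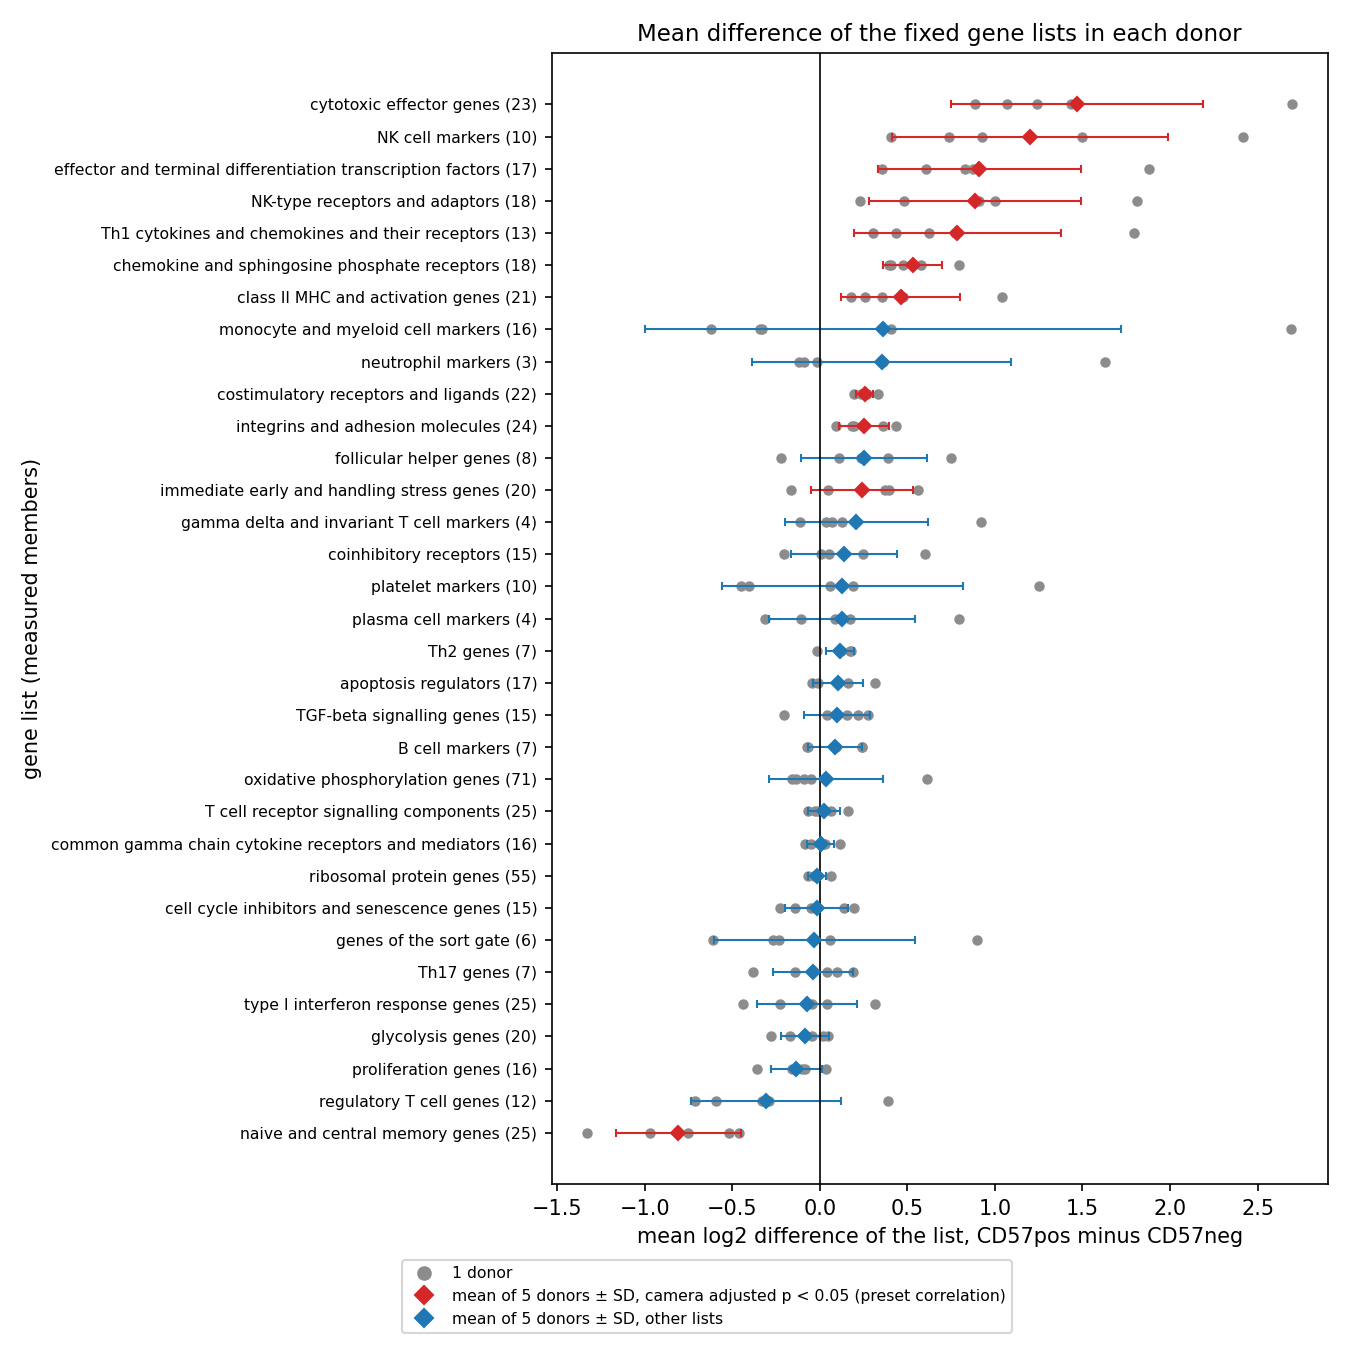
Mean log2 difference (CD57pos minus CD57neg, horizontal axis) of each tested gene list, with measured members in brackets. Grey points are single donors, diamonds with bars the mean ± SD of 5 donors, red where camera with the preset correlation passed; the donor means of the cytotoxic list run from 0.89 to 2.70 and those of the naive and central memory list from -1.33 to -0.46.

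In the fit first described, over all 5 donors with 1 probe set per gene, the remaining lists of T cell biology did not pass camera. In that fit 0 of their members passed over all genes. Some of these lists passed under other settings, which are given with each list. CTLA4, an inhibitory receptor that regulatory T cells carry at high level, differed by -1.18 ± 0.25 (SE), lower in 5 of 5 donors. FOXP3, the lineage factor of regulatory T cells, differed by -0.71 ± 0.24 and GPR15, a homing receptor of the colon, by -0.60 ± 0.18, while TNFRSF1B, a receptor of tumour necrosis factor, differed by 0.38 ± 0.15, higher in 5 of 5 donors without passing. Of 2 other FOXP3 probe sets above the filter, 1 had the other direction. The 12 measured regulatory T cell genes had a median of -0.34, with CTLA4 the 1 that was lower adjusted over the list alone, and camera's adjusted p = 0.208. The median was -0.63 without replicate 1 (adjusted p = 0.00673) and -0.11 without replicate 3 (adjusted p = 0.278), and with donors 2 and 5 only the list passed (-0.35, adjusted p = 0.0113). Of 15 measured coinhibitory receptors (median 0.09, adjusted p = 0.257), KLRG1 was higher and CTLA4 lower adjusted over the list alone, while CD160 and CD244 differed by 0.99 ± 0.31 and 0.66 ± 0.21 without passing; the list's median was -0.03 without replicate 4. Of 8 measured follicular helper genes (median 0.08, adjusted p = 0.257), the transcription factors ASCL2 (1.74 ± 0.41) and BCL6 (0.87 ± 0.26) were higher adjusted over the list alone, ASCL2 from a level below the filter in CD57neg cells (5.28), and the median was -0.01 without replicate 5. The chemokine receptor CCR4 (0.56 ± 0.13) was the 1 of 7 measured Th2 genes that was higher over the list alone (median 0.05, adjusted p = 0.298), and PTGDR2, the Th2 prostaglandin receptor, differed by 0.33 ± 0.19, or 0.20 without replicate 2 and 0.50 without replicate 4. The Th2 median ran from 0.02 without replicate 2 to 0.20 without replicate 3, and the list passed with the mean of all probe sets of a gene (median 0.14, adjusted p = 0.0498). In the 7 measured Th17 genes 0 passed over the list alone; AHR, a ligand-sensing factor, differed by 0.38 ± 0.13 and ABCB1, an efflux pump, by -0.62 ± 0.23. The Th17 median was 0.03, the mean -0.04 and camera's direction up (adjusted p = 0.832); without replicate 3 or 4 the median was -0.03 and -0.02.

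Genes of the cell cycle, survival and signalling gave small medians. SESN1 and SESN3, stress-inducible sestrins, differed by -0.72 ± 0.12 and -0.85 ± 0.20 (SE), lower in 5 of 5 donors, and were the 2 of 15 measured cell cycle inhibitors and senescence genes that were lower adjusted over the list alone. TERF2, a telomere-binding protein, differed by -0.55 ± 0.16 and CDKN2A, which encodes p16, by 0.50 ± 0.17, and neither passed; 2 of 3 other TERF2 probe sets had the other direction. That list had a median of 0.15, or 0.08 without replicate 1 and 0.06 without replicate 3, a mean of -0.02 and camera's direction up (adjusted p = 0.926). FAS, a death receptor of memory T cells, was 1.72-fold higher (0.78 ± 0.15) and the 1 of 17 apoptosis regulators to pass over the list alone (median 0.10, adjusted p = 0.12). The apoptosis list passed without replicate 3 (0.16, adjusted p = 0.0463), after quantile normalization (0.16, adjusted p = 0.0383) and with the stricter filter (adjusted p = 0.048), and its median was 0.05 without replicate 4. BAX, which permeabilises mitochondria, differed by 0.36 ± 0.14. In the TGF-beta list of 15 (median 0.03, adjusted p = 0.605), TGFBR3 (1.35 ± 0.24), a coreceptor, and SMAD7 (1.22 ± 0.27), an inhibitor of the pathway, were higher and the receptor TGFBR2 (-0.74 ± 0.21) lower adjusted over the list alone. SKIL, a corepressor of SMADs, differed by -0.67 ± 0.23, and the TGF-beta median was -0.06 without replicate 3 and -0.01 without replicate 5. Proliferation genes, 16 measured, had a median of -0.11 (adjusted p = 0.606), or 0.08 without replicate 3. ZWINT, a kinetochore protein, differed by -0.73 ± 0.23 and the replication factor MCM7 by -0.37 ± 0.12, while MCM4, another MCM subunit, differed by 0.45 ± 0.16 (higher in 5 of 5 donors, with 1 of 3 other probe sets in the other direction), and 0 passed over the list alone. The 25 T cell receptor signalling components had a median of -0.07, or -0.02 without replicate 3, a mean of 0.02 and camera's direction up (adjusted p = 0.874). Their adaptor SH2D2A differed by 0.73 ± 0.22 and the exchange factor VAV1 by -0.36 ± 0.15, and 0 passed over the list alone. The 16 genes of common gamma chain cytokine receptors and mediators had a median of -0.08, or -0.02 without replicate 4, a mean of 0.01 and camera's direction up (adjusted p = 0.801). IL15RA, which presents interleukin-15, and IL9R differed by 0.57 ± 0.16 and 0.62 ± 0.19, and 0 passed over the list alone.

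Housekeeping and interferon lists lay near 0, and 0 of their members passed over the list alone. Glycolysis genes, 20 measured, had a median of -0.09 (adjusted p = 0.698), with HK2, a hexokinase, at -0.80 ± 0.20 (SE). The 71 oxidative phosphorylation genes had a median of 0.04 (adjusted p = 0.226), or 0.10 without replicate 3 (adjusted p = 0.0447). Without replicate 4 it was -0.13 (adjusted p = 0.206), with the mean of all probe sets of a gene -0.02, and the list's mean was above 0 in 1 of 5 donors. Complex I subunit NDUFA6 was at 0.50 ± 0.16 and the ATP synthase subunit ATP5F1A at -0.34 ± 0.11, and the 1 other probe set of each had the opposite direction. The 55 ribosomal protein genes had a median of -0.02, which turned positive when arrays were centred on their medians (adjusted p = 0.815), with RPS9 at -0.32 ± 0.11. The 25 type I interferon response genes had a median of -0.04, close to 0 and positive after quantile normalization (adjusted p = 0.727), or 0.04 without replicate 3. Of its antiviral genes, MX2 and OAS3 differed by -0.79 ± 0.24 and -0.58 ± 0.18, and OASL by 1.20 ± 0.40, higher in 4 of 5 donors.

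Over all 5 donors, markers of further cell types did not pass camera, except the monocyte and myeloid list with the stricter filter. The monocyte and myeloid list passed without replicate 1, 3 or 5 (median 0.62, 0.63 and 0.70, adjusted p = 0.0272, 0.0412 and 0.00615) and with the stricter filter (adjusted p = 0.041). The monocyte genes CST3 and MNDA differed by 0.55 ± 0.36 and 0.70 ± 0.57 (SE), or 0.27 and -0.01 without replicate 4, where the list's median was -0.23, and 0 of 16 monocyte markers passed over the list alone. CLU (clusterin) at 1.10 ± 0.21 was the 1 of 10 platelet markers that was higher over the list alone (median 0.04, or -0.01 without replicate 4, adjusted p = 0.25); ITGB3, the platelet integrin beta chain, differed by 0.49 ± 0.42, or 0.01 without replicate 4. Of 3 neutrophil markers (median 0.16, or -0.58 without replicate 4 and 0.47 without replicate 1, adjusted p = 0.555), CXCR2 was higher and VNN2 (-0.49 ± 0.18, or -0.32 without replicate 1) lower over the list alone. In the 7 B cell markers (median 0.07, or 0.02 without replicate 4, adjusted p = 0.393), the 4 plasma cell markers (median 0.15, or 0.03 without replicate 3, adjusted p = 0.314) and the 4 gamma delta and invariant T cell markers (median 0.20, or 0.06 without replicate 4, adjusted p = 0.514), 0 passed over the list alone. BLK, a B cell kinase, differed by 0.29 ± 0.14, XBP1, a factor of secretory cells, by 0.30 ± 0.15 and the transcription factor CEBPD by 0.66 ± 0.35; without replicate 4 XBP1 differed by 0.20 and CEBPD by 0.25. With only 2 CD8 T cell markers (CD8A and CD8B, median -0.17) and 1 red blood cell marker (HBB, 0.51 ± 0.26, or 0.24 without replicate 1) measured, these lists were not tested. Leaving out replicate 4 put CD8A at -0.68 and CD8B at -0.70.

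The arrays' facility numbers fell in 2 ranges, each with both groups of its donors. A test for a different CD57pos minus CD57neg difference in each range called 0 of 11176 genes with limma, and 310 genes (2.77%) had an unadjusted p under 0.05. Within the lower range, with 2 donors, 311 genes were higher and 537 lower at an unadjusted p under 0.05, and within the higher range, with 3 donors, 389 and 573; 0 passed adjustment in either. camera with the preset correlation called 10 lists in the lower range and 12 in the higher, against 11 over all donors. The adhesion list did not pass in the lower range (adjusted p = 0.13), where its median was 0.04, nor did the costimulatory list (adjusted p = 0.0695) and the immediate early list (adjusted p = 0.103) in the higher range, where the costimulatory median was 0.17. Lists that passed in the higher range and not over all donors were the regulatory T cell genes (median -0.55, adjusted p = 0.00153), the oxidative phosphorylation genes (0.13, adjusted p = 0.0343) and the monocyte and myeloid markers (0.61, adjusted p = 0.0399).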

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

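All tests of explanations in this part were chosen after the results were seen, as were the NK and monocyte markers named here outside the rule. Named genes, lists and counts of far values were compared within each group of 5 arrays. An array is given where its gap to the nearest other, divided by the range of the group, passed a bound that chance passes in about 1 of 20 groups (5%). That was so for 16 of 224 groups of gene values, 6 of 66 of list means and 2 of 4 of array counts.

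The CD57neg array of replicate 4 stood apart most often. It held 40 genes more than 2 log2 below their median, against 1 to 4 on the other CD57neg arrays (gap 0.923 of the range). CD3D at 11.67 (gap 0.808), CD3G at 11.14 (0.737), the fractalkine receptor CX3CR1 at 6.24 (0.768) and the integrin chain ITGB3 at 5.34 (0.752) were lowest there, and ITGAL at 11.70 (0.799) was highest. The means of the oxidative phosphorylation genes (gap 0.791), the ribosomal protein genes (0.844) and the chemokine and sphingosine phosphate receptors (0.793) were lowest there too.

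Less monocyte RNA on that array than on the other 9 is a candidate explanation: the 16 monocyte and myeloid markers had a median deviation of -2.38 there, 11 of them were among the 40 genes, and the T cell receptor signalling components had -0.00214. LYZ stood at 8.29 against 8.80 to 12.30 on the other arrays and S100A8 at 7.38 against 10.40 to 11.90, although the sort for CD3 and CD4 would remove most monocytes. Loss of single probe sets is argued against for the probe sets above the filter that lay that far below. Other probe sets of their genes, 61 when counted once for each far probe set, had a median deviation of -2.59 there. Lower expression throughout that donor's cells is argued against too, since the 40 genes had a median deviation of 0.65 on the donor's CD57pos array. Other lists also lay lower there, the NK cell markers by a median deviation of -1.24, the cytotoxic genes -1.05 (7 of the 40 genes), the class II and activation genes -0.722 and the oxidative phosphorylation genes -0.694, and whether monocyte RNA accounts for these was not tested, nor was another biological explanation.

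Many values far below the gene's median were seen on the CD57pos arrays of replicates 1, 3 and 4 (73, 163 and 105 genes). Whether those genes were lower in the cells was followed through other probe sets. The check took every probe set with a median above the filter that lay that far below, not only 1 per gene. Other probe sets of the same genes were counted once for each far one and each array, so genes with many probe sets weigh more. Of 1844 so counted, 19.9% lay 1 log2 or more below their medians on the same array. That argues against lower expression as the general reason for such far probe sets. It does not decide for the 73, 163 and 105 genes, which were not followed on their own. The 1844 other probe sets had a median deviation of -0.235, as loss of single probe sets on those arrays would give. Such loss may come from little RNA before amplification, but the amount was not tested. Loss would not give high values, and 12, 48 and 67 genes lay more than 2 log2 above their median on these 3 arrays. That count was 13 and 2 on the CD57pos arrays of replicates 2 and 5, and 0 to 4 on the CD57neg arrays. Degraded RNA had no sign in replicates 3 and 4 in the mean 3' minus 5' difference of the GAPDH and ACTB controls (0.442 and 0.376). Both lay below the highest CD57neg array (0.536). In replicate 1 that difference was 0.77, above every CD57neg array. The RNA had been amplified, and whether these controls would still show degradation was not tested. Degraded RNA therefore stays open.

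The higher cytotoxic genes of CD57pos cells, with a median difference of 1.28, could come from NK or CD8 T cells in the sort, or from the CD57pos CD4 T cells themselves. The sort as described used no marker that parts naive from memory cells, so the share of each in either group is not known. Whether such shares account for the difference was not tested. The 6 NK-restricted markers had a median difference of 0.957, above 0 and below that of the cytotoxic list except without replicate 5 (1.29 against 1.26), and of 0.531 without replicate 4: NCR1 differed by 0.50, KLRF1 by 1.86, TYROBP by 1.01 and FCER1G by 0.91 (0.53 and 0.36 without replicate 4), while NCAM1 (0.40) and SH2D1B (1.43) were dimmer than the filter allowed, so that their differences are uncertain. NK cells and CD57pos T cells cannot be told apart by these, since cytotoxic T cells carry some of the same receptors and monocytes carry TYROBP and FCER1G. The gate on CD3 would remove NK cells, but high LYZ and S100A8 on most arrays leave open how fully it removed cells without CD3. More CD8 T cells in the CD57pos sort than in the CD57neg sort are argued against in replicates 2 and 5. There the mean of CD8A and CD8B differed by 0.181 and -0.613 while the cytotoxic mean differed by 1.44 and 0.887. In replicates 1 and 3 the CD8 mean differed by -0.671 and -1.66. Loss of single probe sets on their CD57pos arrays could lower it too, so these values do not decide. CD8B lay near the filter in both groups (6.19 and 6.54). CD8 T cells at a like share in both sorts are not excluded, since those in the CD57pos sort would carry CD57. CD8A lay at 7.15 in CD57pos and 7.14 in CD57neg cells, above the filter. In replicate 4 the mean of CD8A and CD8B differed by 1.90 and monocyte markers by 2.96. CD8 T cells thus cannot be told apart from the other differences between the 2 arrays of that donor.

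On the CD57neg array of replicate 3, GZMH at 9.30 (gap 0.743) and SLAMF7 at 7.66 (0.71) were highest, and NIBAN1 at 9.55 (0.753), the mean of the regulatory T cell genes at 7.58 (0.719) and that of the immediate early genes at 8.64 (0.843) were lowest. The CD57pos array of replicate 3 had the lowest CD3G, 11.49 (0.796), and TGFBR2, 9.39 (0.816), and the highest mean of plasma cell markers, 8.91 (0.726). CCR7 was lowest, 9.60 (0.745), and CD58 highest, 10.09 (0.78), on the CD57pos array of replicate 4. FHIT was lowest on the CD57neg array of replicate 2, 8.92 (0.907), CDKN2A on that of replicate 5, 5.33 (0.741), and ITGB2 on that of replicate 1, 11.43 (0.714). IL9R was highest on the CD57pos array of replicate 5, 7.35 (0.803). The CD57neg array of replicate 1 held 4 genes more than 2 log2 above their median against 0 to 1 on the others (0.75).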

How the results depend on the processing

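Array quality weights, donors 1, 2 and 5 only, and donors 2 and 5 only were tested after the results were seen. Under all settings not named in the next sentence, limma called 0 genes. It called 6 higher and 2 lower with no replicate block, 38 and 23 with a random replicate block, and 29 and 14 with array quality weights. A change of the block leaves the estimates as they were. The fixed block leaves 4 residual degrees of freedom, fewer than no block or a random one, and the random block's correlation was 0.0888. How far this accounts for the added calls was not tested, nor was the cause for the weights. Genes higher at an unadjusted p under 0.05 numbered 1764 with no filter (the cause was not tested), 1012 with each probe set tested (probe sets counted, not genes), and 311 and 389 in the lower and higher facility number ranges (fewer donors); genes lower numbered 1991, 537 and 573 in the last 3. camera called 7 lists with no filter and 0 with an estimated correlation, and fry called 2 (chemokine receptors and costimulatory genes); for the filter the cause was not tested. The fit without the block changed no list call. With donors 2 and 5 only, the immediate early list's median was -0.0414 (adjusted p = 0.907 in place of 0.0177); the cause was not tested.

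Leaving out 1 donor at a time gave 0 to 0 genes higher and 0 to 0 lower, 495 to 605 higher and 734 to 1076 lower at an unadjusted p under 0.05, 11 to 13 lists, and 0 to 0 genes with an effect that differed by facility number range. Over all settings, lists kept their side of the threshold 642 times, lost the call 33 times, gained it 14 times and turned 1 time; named genes kept theirs 2092 times and gained a call 49 times. In 34 of 1596 pairs of a named gene and a setting that leaves no donor out, the sign differed. Genes near the filter at 5.93 lie close to background, where RMA compresses differences.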

Other observations

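The genes of the first paragraph here, all outside the fixed lists, and the fit with array quality weights were chosen after the results were seen; the splits of the arrays were planned.

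Several genes of no list were called both with the donor as a random block and with array quality weights. PTGDS, which makes prostaglandin D2, differed by 1.82 ± 0.30 (SE, n = 5) with the random block (limma's adjusted p = 0.042) and by 1.53 ± 0.19 with the weights (adjusted p = 0.0414). PRR5L, a partner of the kinase complex mTORC2, differed by 1.93 ± 0.34 and 1.96 ± 0.22 (adjusted p = 0.0447 and 0.0414). NIBAN1, a stress-induced regulator of translation, and USP46, a deubiquitinase, differed by 0.92 ± 0.11 and 1.04 ± 0.13 with the random block, both with adjusted p = 0.0263. Lower in CD57pos cells were STAP1, a signalling adaptor (-1.19 ± 0.21, adjusted p = 0.0457), the kinase MAK (-1.24 ± 0.21, adjusted p = 0.0434), AGMAT, which is related to agmatinases (-1.05 ± 0.16, adjusted p = 0.0402), LYG1, a lysozyme-like protein (-0.99 ± 0.17, adjusted p = 0.0447), and RETREG1, a receptor for the turnover of the endoplasmic reticulum (-0.86 ± 0.14, adjusted p = 0.042). All 9 had 1 direction in 5 of 5 donors. With the donor as a fixed block each had adjusted p = 0.112.

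Other splits of the 10 arrays into groups of 5 were refitted with the donor as a block, 100 of them with the real one included. The count of genes past the adjusted threshold was 0 in the real split and 1 in the highest other; with a real count of 0 all 100 splits give as many whatever the values, so this count says nothing about chance. For genes at an unadjusted p under 0.05 the real split gave 1616 and the highest other 1900, and 2 of 100 splits gave as many. Most of the others part the arrays of 1 or 3 donors, rest on fewer donors than the real split and repeat each other, so that share does not exclude chance for a paired design. Of the 16 splits that part all 5 donors' arrays, the highest other gave 934, and 16 splits are too few for a share under 0.05. The real split called 11 lists with the preset correlation and the highest other 12, and 19 of 100 splits gave as many, so chance cannot be excluded for that count. Genes with 1 direction in all 5 donors numbered 1888 in the real split and 1271 in the highest other of those 16 splits, where 1 split, the real one, gave as many.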
